A study of Mus musculus with 8 samples.

How the data were processed

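RNA sequencing libraries were made from 8 samples of mouse cells sorted out of embryoid body cultures, with RNA from a silica column kit and a stranded mRNA library kit, per the labels' protocols. The labels assign 4 libraries to endocardial cells (A, C, E and G) and 4 to endothelial cells (B, D, F and H). They do not say that the libraries come from separate cultures or sorts, so p-values measure only the spread between these samples, which may be technical. The sort markers, the culture day and the stem cell line are not given in the sources used here. Each library has a letter of its own, and no label pairs a library of one group with one of the other, so the comparison was made without a block.

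The deposited values are estimated counts per gene symbol, since Salmon, a transcript quantifier, is named per the submitters' processing notes, as are DESeq2 and genome build mm10. The deposited estimated counts are whole numbers in every library and sum to different totals, so they had been rounded and not brought to a common total before deposit. Versions, the transcript set, how transcripts were summed to genes and any filter are not given in the sources used here. Salmon assigns reads shared between transcripts by a model, so values of near-identical gene copies such as the hemoglobin and histone genes are uncertain. Rounding was applied again before the count tests and changed nothing. Symbols were matched to the GENCODE M21 annotation of GRCm38 (the same assembly as mm10), which holds 32697 of the 34536 symbols and 13628 of the 13817 tested. Coordinates are from that annotation, 1-based, and cover the whole gene.

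Counts were filtered with edgeR's filterByExpr (minimum count 10, minimum total 15), scaled by TMM and tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F-test with robust estimation, with endocardial minus endothelial as the coefficient and all 8 libraries in the fit. The common biological coefficient of variation was 0.239. The p-values were adjusted by the Benjamini-Hochberg method over the 13817 tested genes, and a gene was called at an adjusted p below 0.05. Each SE is the absolute log2 fold change divided by the square root of F. CPM values are counts relative to the TMM-scaled library total, brought to the same total in every library, and means and SDs are over 4 libraries. Gene lists of at least 5 tested genes were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) at a preset correlation of 0.01, two-sided, and adjusted over the 30 lists. Camera compares a list with all other tested genes. Its estimated correlation, its rank form and fry, a test of the list alone, were alternatives. The list level of a library is the mean log2 CPM of the list's tested members. Shares of counts were compared by two-sided exact permutation tests over all assignments of 4 against 4 libraries, adjusted over 7 classes. Principal components were computed on log2 CPM of the 500 most variable genes.

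The lists and the rule for named genes were fixed before the data were examined. The rule took the 12 genes with the largest increase and the 12 with the largest decrease among genes with an adjusted p below 0.05, at least a 2-fold difference, a mean of at least 5 CPM in the higher group, no overlap between the groups and a symbol that is not a predicted model. It added, for each list, up to 4 members with the smallest p. It also added, whatever their result, Nfatc1, Npr3, Pecam1, Cdh5, Kdr, Tek, Gata4, Hand2, Bmp2, Bmp4, Nrg1, Edn1, Notch1, Tal1, Runx1, Etv2, Hey2, Tnnt2 and Nkx2-5. The vascular and cardiac lists were pan-endothelial, endocardial, cardiac mesoderm and progenitor, cardiomyocyte, endothelial-to-mesenchymal transition and cushion, arterial, venous and lymphatic, VEGF and angiopoietin receptors and sprouting, and flow-responsive. The signalling lists were BMP, Notch, Wnt and secreted signals of vessels and endocardium. Lists of other cells that the sort could hold were hemogenic and blood, smooth muscle and mural, mesenchyme and fibroblast, epicardial, pluripotency, endoderm and yolk sac, epithelial, neural ectoderm and neuron, and skeletal muscle. The lists of cell state were cell cycle, immediate early and dissociation stress, extracellular matrix, glycolysis, hypoxia, oxidative phosphorylation, sterol synthesis, and interferon response and antigen presentation. Some lists share members, such as Plxnd1, Notch4 and Flt4, so their counts are not independent.

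The alternatives fixed before the data were examined were DESeq2 1.42.0 with its own size factors, limma voom with sample quality weights, relative log expression and upper-quartile scaling, no filter on low counts, a stricter filter (at least 1 CPM in 4 libraries and a total of 100), leaving out mitochondrial, hemoglobin and the 10 most abundant genes, estimation without robustness, 1 surrogate variable from sva 3.50.0, a threshold of 0.01 and leaving out each library in turn. A fit with libraries of neighbouring letters as a block was added after the second principal component was seen to hold them together.

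The edgeR step was tested on simulated counts for 13654 genes drawn from the means and totals of these libraries. It recovered 53% of the 100 genes changed 2-fold and 88% of the 100 changed 4-fold, all in the right direction, and 14 of its 155 calls (9.03%) were genes that had not been changed. In that setting a difference of 2-fold was often missed at this number of libraries. The changed genes were taken only from those above a minimum mean count. Counts were drawn independently, without the links between libraries or genes seen in the data. These shares therefore need not hold for genes with fewer counts or for the real libraries. Nkx2-5 did not pass the count filter and was not tested. Some genes that the rule for named genes selects are not reported here.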

Results

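RNA was sequenced from mouse cells sorted by fluorescence out of embryoid bodies, the aggregates in which pluripotent stem cells differentiate in culture. The labels give 2 groups of 4 libraries, endocardial cells (libraries A, C, E and G) and endothelial cells (libraries B, D, F and H). The endocardium is the endothelial layer that lines the heart, and the series asks how its signals bear on the formation of heart muscle in culture. The markers used for the sort were not given in the sources used here, and a sort on endothelial or endocardial genes, or one of lower purity in one group, would itself shape the levels of such genes. The values were estimated read counts per gene symbol, and the total per library ran from 6677667 to 11369363. The mean total was 8754710 ± 841716 (SD, n = 4) in the endocardial libraries and 8948761 ± 1927669 (SD, n = 4) in the endothelial libraries, a difference within the spread between libraries (two-sided exact permutation p = 0.886). A gene with a count of 0 could at these depths have had up to between 0.264 and 0.449 CPM, the value of 3 counts, which covers counting error only. Of 34536 symbols, 11808 had no count in any library and 13817 had enough counts to be tested.

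Libraries separated by labelled cell type along the first principal component, which held 54.1% of the variance of the 500 most variable genes. The endocardial scores lay between 7.63 (library E) and 29.2 (library A), and the endothelial scores between -39.7 (library F) and -3.54 (library B). The second component held 22.1% of the variance and placed libraries with neighbouring letters near each other, with A at 19.7 and B at 15.8, and with G at -21.5 and H at -17.2. Spearman correlations across genes were 0.969 to 0.987 between endocardial libraries, 0.951 to 0.984 between endothelial libraries and 0.93 to 0.98 between the groups, and genes are not independent replicates. No pair of libraries was as alike as sampling noise would make it, since the chi-square per degree of freedom was 7.996 or more for every pair.

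**Figure D1:**
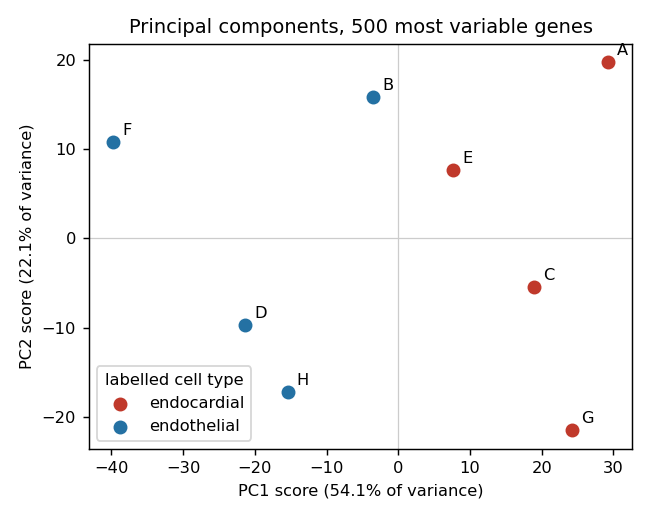
Scores of the 8 libraries (points, with the library letter) on the first principal component (horizontal axis, 54.1% of the variance) and the second (vertical axis, 22.1%) of the 500 most variable genes, coloured by labelled cell type. All 4 endocardial libraries lie above 0 and all 4 endothelial libraries below 0 on the horizontal axis, and library F lies farthest from the rest at -39.7.

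The comparison of the 2 groups asks how cells labelled endocardial differ in their transcripts from cells labelled endothelial. The endocardial libraries had more Nfatc1, a transcription factor of the endocardium, at 48.9 ± 5.07 CPM against 11.5 ± 2.53 (SD, n = 4 each), which is 4.26-fold higher. They also had more of most genes shared by all endothelium, among them Cdh5, the adherens junction cadherin of endothelial cells, at 132 ± 17.3 CPM against 16.1 ± 1.11 (8.20-fold). The pan-endothelial genes had a median log2 fold change of 1.86, and Nfatc1 had one of 2.09. Whether Nfatc1 differed beyond the shared endothelial genes was not tested. The endothelial libraries had more transcripts of some genes known from pluripotent cells, epithelium and the neural plate, such as Fgf4, Cdh1, Sox1 and Pax6. Cdh1, the epithelial cadherin, was at 120.7 ± 69.2 CPM in the endothelial and 27.7 ± 11.2 CPM in the endocardial libraries. Of heart muscle and cardiac progenitor genes, edgeR called 0 over all genes, with 6 and 4 at an unadjusted p under 0.05, while DESeq2 and limma each called 1 of heart muscle and 3 of progenitors.

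By edgeR's quasi-likelihood test with a Benjamini-Hochberg adjusted p below 0.05, 196 genes were higher and 160 lower in the endocardial libraries, 356 of the 13817 tested. Of these, 284 differed at least 2-fold, 152 higher and 132 lower. At an unadjusted p under 0.05 there were 2023 genes. In all 356 called genes the 4 libraries of one group lay apart from the 4 of the other, as did 9.76% of all tested genes, where chance gives 2.86%. The number of calls depended on single libraries. It was 189 without A, 157 without C, 138 without D, 135 without E and 153 without G, and it was 457 without B, 290 without F and 326 without H. DESeq2 called 860 genes and limma with voom weights 975, and in both the lower calls outnumbered the higher, at 530 against 330 and 565 against 410.

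The 12 genes with the largest increase under the rule for named genes were Slc32a1, Oit3, Gad2, Ptprb, Sost, Cdh5, Sox7, Dusp2, Erg, Nos3, Ccm2l and Adgrl4. Slc32a1, the vesicular transporter of the transmitter GABA (mouse build GRCm38, chromosome 2, 158610767 to 158615748, protein-coding), had 12.7 ± 3.32 CPM in the endocardial and 0.737 ± 0.295 CPM in the endothelial libraries (SD, n = 4). Its log2 fold change was 4.12 (SE 0.35, adjusted p = 0.00021). Gad2, which makes GABA (chromosome 2, 22622205 to 22693874), had a log2 fold change of 3.27 (SE 0.28, adjusted p = 0.000205). Oit3 (chromosome 10, 59422958 to 59441778) had a log2 fold change of 4.12, and its mean rose from 0.721 ± 0.341 to 13.1 ± 3.14 CPM. The receptor phosphatase gene Ptprb, which acts at endothelial junctions, was 9.24-fold higher, the transcription factor gene Erg 7.08-fold and Nos3, the endothelial nitric oxide synthase, 6.85-fold. Sost, a secreted Wnt and BMP antagonist, was at 7.85 ± 2.04 against 0.837 ± 0.451 CPM. Of the 12, 11 were called in all 8 fits that leave out 1 library. Ccm2l was called in 6, with an adjusted p of 0.0576 without D and 0.0512 without E.

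Genes with the largest decrease under the rule included Fgf4, Alox15, Fezf2, Fut9, Wnt8b, Pcdh8, Sox1, Nfasc, B3gnt7 and Nrcam. Alox15, a lipoxygenase (chromosome 11, 70344152 to 70352031), had 0.59 ± 0.298 CPM in the endocardial and 6.63 ± 1.53 CPM in the endothelial libraries (SD, n = 4), a log2 fold change of -3.44 (SE 0.39, adjusted p = 0.00151). Nfasc, a neuronal adhesion molecule (chromosome 1, 132564690 to 132741797), had a log2 fold change of -2.87 (SE 0.33, adjusted p = 0.00161). Fgf4, a growth factor gene active in pluripotent cells (chromosome 7, 144847367 to 144865243), was at 0.923 ± 0.971 against 12.1 ± 11.3 CPM (log2 fold change -3.67, SE 0.79, adjusted p = 0.0441). Fezf2, a forebrain transcription factor gene, had a log2 fold change of -3.31, and Wnt8b one of -3.19. Of these 10 genes, only Alox15 and Nfasc kept their call in all 8 fits that leave out 1 library. Fut9 was called in 1 of the 8, and Fgf4, Fezf2, Wnt8b, Pcdh8, Sox1 and B3gnt7 in 2 each. Without library F, Fgf4 had an adjusted p of 0.0529 and Sox1 one of 0.0608.

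**Figure D2:**
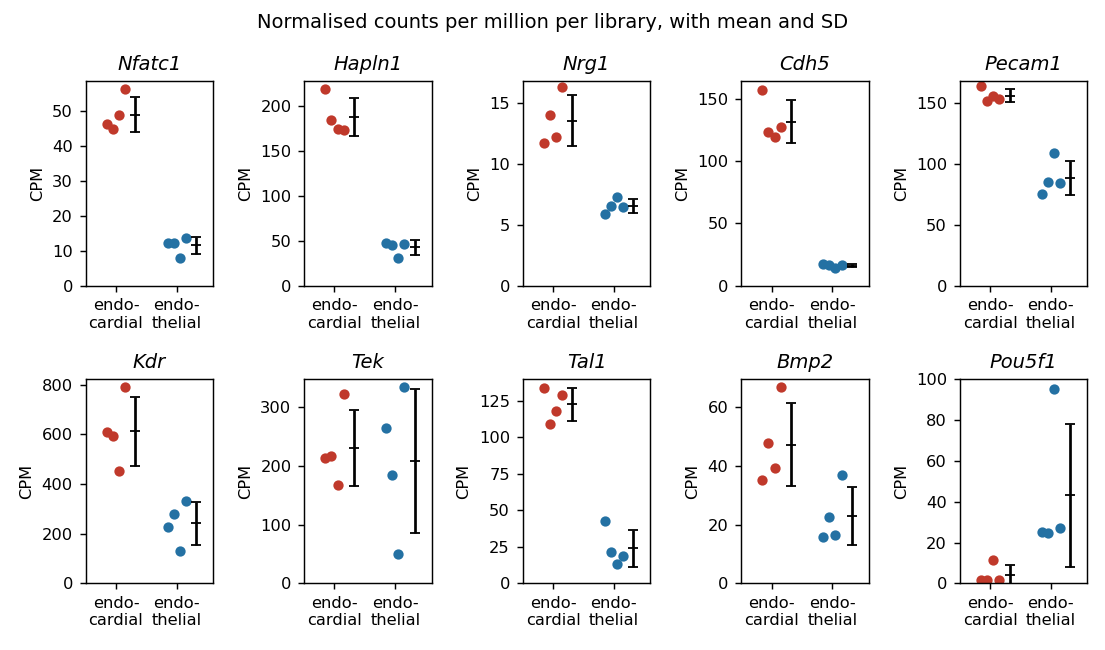
Normalised CPM (vertical axes, each from 0) of 10 genes in each of the 4 endocardial (red) and 4 endothelial (blue) libraries, with the mean (dash) and SD (bar) of each group. The groups do not overlap for Nfatc1, Hapln1, Nrg1, Cdh5, Pecam1, Kdr, Tal1 and Pou5f1, they overlap for Tek and Bmp2, and library F holds the highest Pou5f1 value.

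The 30 gene lists fixed before the data were examined were tested with limma's camera at a preset inter-gene correlation of 0.01. Of these lists, 11 were called higher and 3 lower in the endocardial libraries, 14 in all. With a correlation estimated from the data, 1 list stayed called, the pan-endothelial genes, and 0 with neighbouring letters as a block. Without library F the endocardial and the VEGF and angiopoietin receptor lists were called too (adjusted p = 0.0392 each). Other splits of the 8 libraries into 4 and 4 also called many lists, up to 18, and 5 of the 35 splits, the real one included, called 14 or more.

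Most pan-endothelial genes were higher in the endocardial libraries, and none was called lower. Of 30 tested, 23 were called higher (27 adjusted over the list alone), with a median log2 fold change of 1.86 (camera adjusted p = 6.98e-44, and adjusted p = 0.00123 with an estimated correlation, but 0.0663 with that and libraries of neighbouring letters as a block, a fit added after the data were seen). Cdh5 (chromosome 8, 104101625 to 104144511) had a log2 fold change of 3.04 (SE 0.13, adjusted p = 3.96e-06), the junction protein gene Esam 2.43 (SE 0.11, adjusted p = 4.5e-06) and Rasip1, which acts in vessel lumen formation, 2.61 (SE 0.15). Pecam1, a marker of endothelium (chromosome 11, 106654217 to 106750628), differed less, at 156.7 ± 5.15 against 88.6 ± 14.1 CPM (SD, n = 4), a 1.77-fold difference (adjusted p = 0.0069). The 7 not called included Tek, the angiopoietin receptor, at 230.0 ± 65.2 and 207.9 ± 122 CPM (log2 fold change 0.15, SE 0.47, and -0.20 without F), and Etv2, an early regulator of the endothelial lineage (1.57, SE 0.38, adjusted p = 0.0622). Over the same libraries, the mean log2 CPM of the pluripotency list was 3.32 to 5.98 in the endothelial and 1.09 to 3.25 in the endocardial group. Without library F, which had the highest pluripotency level, 25 pan-endothelial genes were called higher and the median was 1.88.

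Of 24 VEGF and angiopoietin receptor and sprouting genes, 7 were higher (9 adjusted over the list alone) and 17 were not called, 5 of the 24 having a negative log2 fold change, with a median log2 fold change of 0.59 (camera adjusted p = 4.85e-08, and adjusted p = 0.0623 with an estimated correlation). Among them Tie1 was 6.22-fold, Flt4, the receptor for VEGF-C, 4.18-fold, Plxnd1, a semaphorin receptor, 3.28-fold and Flt1 2.33-fold higher. Kdr, the main VEGF receptor (chromosome 5, 75932827 to 75978458), was at 611.7 ± 138 against 242.0 ± 86.2 CPM (log2 fold change 1.34, SE 0.28, adjusted p = 0.0347). Kdr kept its call in 2 of the 8 fits that leave out 1 library, those without F or H, and its adjusted p was otherwise up to 0.0989. Of 13 flow-responsive genes, Nos3 and the caveolin gene Cav1 (log2 fold change 1.95, adjusted p = 0.0332) were higher, also when adjusted over the list alone, with a list median of 0.41 (camera adjusted p = 9.59e-05, and adjusted p = 0.123 with an estimated correlation). Cav1 was called in 3 of the 8 fits that leave out 1 library, and Nfe2l2 and Slc9a3r2 of this list, at 0.38 and 0.41, were not called.

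Some arterial and some venous or lymphatic genes were higher. Of 17 arterial genes, 4 were called higher, namely Notch4 (log2 fold change 1.75), Sox17 (1.84), the connexin gene Gja4 (1.92) and Tspan8 (1.94). Adjusted over the list alone, 6 were higher and 1 lower, and the list median was 0.36 (camera adjusted p = 0.00298, and adjusted p = 0.123 with an estimated correlation). Of 14 venous and lymphatic genes, 5 were called higher, Flt4 (2.06), the scavenger receptor gene Stab1 (2.03), the hyaluronan receptor gene Lyve1 (2.60), the apelin receptor gene Aplnr (1.36) and Prox1 (0.58). Prox1 was named after its value was seen. Adjusted over the list alone, 8 were higher and 1 lower, with a median of 0.97 (camera adjusted p = 1.46e-05, and adjusted p = 0.123 with an estimated correlation). Notch4, Sox17, Flt4 and Stab1 were called in all 8 fits that leave out 1 library, Gja4 in 5, Aplnr in 3, and Tspan8 and Lyve1 in 2 each. Hey2, an arterial and endocardial Notch target, had a log2 fold change of 0.90 (SE 0.24, adjusted p = 0.0818).

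Of 17 tested endocardial genes, 4 were higher, also when adjusted over the list alone, and the list median was 0.40 (camera adjusted p = 5.66e-06, and adjusted p = 0.123 with an estimated correlation). They were Nfatc1, Hapln1, which codes for a protein linking hyaluronan to proteoglycan in the cardiac jelly, Plxnd1 and Nrg1, a growth factor by which endocardium acts on trabecular heart muscle. Nfatc1 (chromosome 18, 80606205 to 80713071) had a log2 fold change of 2.09 (SE 0.17, adjusted p = 0.000187) and Hapln1 (chromosome 13, 89539796 to 89611652) of 2.14 (SE 0.16, adjusted p = 8.52e-05). Hapln1 was at 188 ± 21.2 against 42.8 ± 8.12 CPM (SD, n = 4), with its lowest value in library F. Nrg1 (chromosome 8, 31814551 to 32884029) was at 13.6 ± 2.1 against 6.55 ± 0.582 CPM (log2 fold change 1.05, SE 0.18, adjusted p = 0.0149). Nrg1 lost its call without C (adjusted p = 0.0679), D (0.0576) or G (0.0532). Plxnd1 had a log2 fold change of 1.71. The pan-endothelial genes had a median of 1.86, so these 4 differences were not told apart from the one in endothelial genes at large. Other genes used as endocardial markers were not called. Npr3 had a log2 fold change of 0.30 (SE 0.37, adjusted p = 0.794), Gata4 of 0.54 (SE 0.31, adjusted p = 0.507) and Hand2 of -0.02 (SE 0.31, adjusted p = 0.99).

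Heart muscle and progenitor genes were called or not depending on the tool, as given below. Tnnt2, cardiac troponin T, was at 64.0 ± 15.8 in the endocardial and 35.5 ± 13.4 CPM in the endothelial libraries (SD, n = 4; log2 fold change 0.85, SE 0.28, adjusted p = 0.16). The cardiomyocyte list had 19 tested genes, of which 0 were called by edgeR over all genes and 0 adjusted over the list alone, with 4 above and 2 below 0 at an unadjusted p under 0.05 1 called by DESeq2 or by limma and 3 with libraries of neighbouring letters as a block. Its median was 0.62 (camera adjusted p = 0.00471, and adjusted p = 0.418 with an estimated correlation), with Actc1 at 1.08, Myl4 at 1.05 and Tnnc1 at 0.99. Of 16 cardiac mesoderm and progenitor genes, edgeR called 0 over all genes (4 at an unadjusted p under 0.05, and 3 each by DESeq2, by limma and with that block). Adjusted over the list alone, 2 were higher and 1 lower, and the median was 0.31 (camera adjusted p = 0.0484, and adjusted p = 0.632 with an estimated correlation). That list was not called without B (adjusted p = 0.0608), E (0.064), F (0.315) or G (0.104). Its smallest p-values belonged to the channel gene Hcn4, at -0.68 (adjusted p = 0.0609), and the transcription factor gene Mef2c, at 1.08 (adjusted p = 0.0653), followed by Foxh1 at 0.68 and Smarcd3 at 0.42. Nkx2-5 was too low to test, with a count of 16 in library E, 13 in C and 0 in A.

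Among signals that vessels and endocardium secrete, Igf1 was higher at 29.2 ± 3.91 against 8.16 ± 2.81 CPM (SD, n = 4; adjusted p = 0.00396). Pdgfb, which recruits mural cells, was also higher, with a log2 fold change of 1.37 (adjusted p = 0.016), as was Nrg1. Pdgfb lost its call without D (adjusted p = 0.0666) or E (0.0639). These were 3 of 33 tested genes (4 higher and 1 lower adjusted over the list alone), and the list was not called (median 0.17, camera adjusted p = 0.164), though it was without A (0.028) or H (0.0414). Bmp2, which acts in the atrioventricular canal (chromosome 2, 133552159 to 133562885), was at 47.2 ± 14.1 against 22.9 ± 9.76 CPM (log2 fold change 1.05, SE 0.30, adjusted p = 0.11). It was called by DESeq2 (adjusted p = 0.0131), limma (0.0161), with 1 surrogate variable (0.00291), with neighbouring letters as a block (0.000953) and without H (0.0228), and over all alternatives its adjusted p reached 0.24. Bmp4 was at 173 ± 31.9 and 151.6 ± 57.2 CPM (log2 fold change 0.19, SE 0.25), Edn1 had a log2 fold change of 0.82 (SE 0.64, adjusted p = 0.648) and Slit2 one of -0.54 (adjusted p = 0.105).

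The BMP, Notch and Wnt lists had members on both sides and none of the 3 lists was called. Of 27 BMP genes, 1 was higher, the endothelial BMP receptor gene Acvrl1 (log2 fold change 1.08, adjusted p = 0.0318, called in 2 of 8 fits that leave out 1 library). Adjusted over the list alone, 2 were higher and 3 lower, with Bmpr1b at -1.99, Chrdl1 at -1.36 and Chrd at -1.10 (camera adjusted p = 0.905). The list's median was 0.07, its mean -0.10 and its camera direction downward. Of 17 Notch genes, Notch4 was higher (adjusted p = 0.00993) and the ligand gene Dll1 lower (-1.78, adjusted p = 0.0258, called in 3 of 8 fits), and adjusted over the list alone 3 were higher and 2 lower (median 0.09, camera adjusted p = 0.527). Dll4 had a log2 fold change of 1.89 (SE 0.47, adjusted p = 0.0704), Lfng of -1.33 and Notch1 of 0.36 (SE 0.20, adjusted p = 0.465). Of 25 Wnt genes, Lgr5, a receptor for R-spondins, was higher (1.46, adjusted p = 0.0147) and the Wnt antagonist gene Frzb lower (-0.93, adjusted p = 0.0111). Lgr5 lost its call without C (adjusted p = 0.0654) or G (0.0538). Adjusted over the list alone 4 were higher and 4 lower. The median was 0.03, the mean -0.10, and the camera direction downward (camera adjusted p = 0.881), with Wnt5b at -1.31 and Fzd10 at 0.66. With neighbouring letters as a block, a fit added after the data were seen, edgeR called more genes of these lists. They were 2 BMP genes higher and 3 lower, 5 Notch genes higher and 1 lower, and 3 Wnt genes higher and 5 lower. Dll4 was among them (adjusted p = 0.00188).

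How many hemogenic and blood genes were called higher in the endocardial libraries depended on the fit. Of 30, edgeR called 5 higher (9 adjusted over the list alone), DESeq2 9, limma 10 and the fit with neighbouring letters as a block 18, with a median log2 fold change of 1.17 (camera adjusted p = 1.87e-09, and adjusted p = 0.418 with an estimated correlation). Tal1, a transcription factor of blood and endothelial progenitors, was at 122.7 ± 11.4 against 24.1 ± 12.7 CPM (SD, n = 4; log2 fold change 2.34, SE 0.31, adjusted p = 0.00485). Lmo2 had a log2 fold change of 2.05, Gata2 of 2.03, Ikzf1 of 2.50 and Gfi1b, named after its value was seen, of 2.40. Ikzf1 kept its call in 2 of the 8 fits that leave out 1 library, and Tal1, Lmo2 and Gata2 in all 8. Runx1, needed for blood to arise from endothelium, had a log2 fold change of 1.42 (SE 0.33, adjusted p = 0.0578). The share of counts from hemoglobin genes was 0.0792% ± 0.049 in the endocardial and 0.0854% ± 0.112 in the endothelial libraries (two-sided exact permutation p = 1), with library B at 0.254% and A at 0.149%. The list's mean level was highest in A (5.43 log2 CPM) and B (4.65) of the respective groups.

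**Figure D3:**
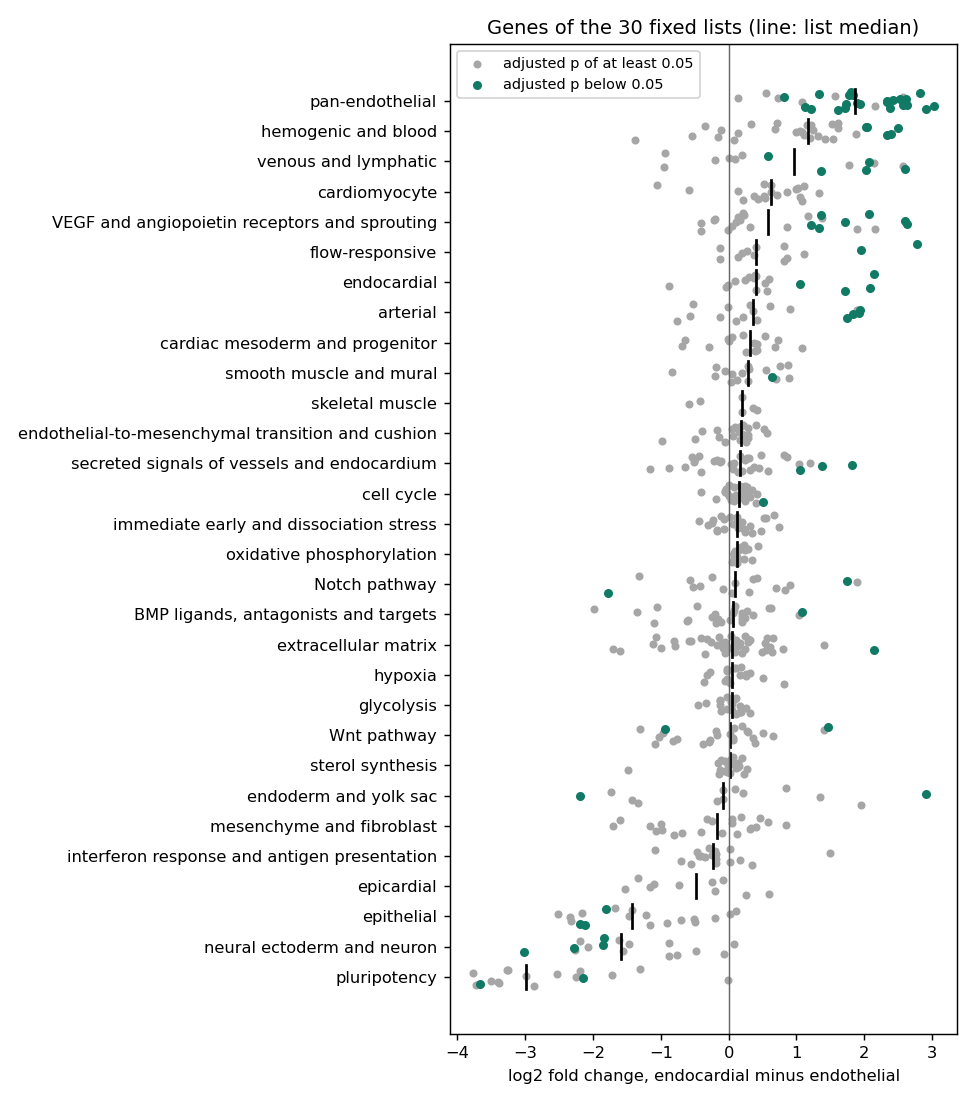
Log2 fold change, endocardial minus endothelial (horizontal axis), of every tested gene (points) of the 30 gene lists (vertical axis), with green for an adjusted p below 0.05, grey for other genes and a line at each list's median. The median is 1.86 for the pan-endothelial list at the top and -2.99 for the pluripotency list at the bottom.

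All 17 tested genes of pluripotent cells had a negative log2 fold change, endocardial minus endothelial, though edgeR called few of them, with a median of -2.99 (camera adjusted p = 6.9e-12, and adjusted p = 0.234 with an estimated correlation). Over all genes edgeR called 2 of them, Fgf4 and the Nodal co-receptor gene Tdgf1 (-2.15, adjusted p = 0.0315), and 16 adjusted over the list alone, while DESeq2 called 10, and 15 were called with libraries of neighbouring letters as a block. Pou5f1, a core pluripotency factor, was at 4.07 ± 4.96 in the endocardial and 43.2 ± 34.9 CPM in the endothelial libraries (SD, n = 4; log2 fold change -3.38, SE 0.77, adjusted p = 0.0569), and Sox2 at 13.1 ± 9.7 and 60.4 ± 36.4 CPM (adjusted p = 0.0752). With that block, a fit added after the data were seen, edgeR called both Pou5f1 (adjusted p = 0.00014) and Sox2 (0.000122). Library F had the highest list level of its group (5.98 log2 CPM, others 3.32 to 4.10), and E of the endocardial group (3.25, others 1.09 to 1.32). Without F the list median was -1.86 and 2 genes were called. Tdgf1 kept its call in 3 of the 8 fits that leave out 1 library.

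Some epithelial and neural genes were also lower in the endocardial libraries. Of 19 epithelial genes, 3 were lower (12 adjusted over the list alone, and 11 with neighbouring letters as a block), namely Cdh1 (log2 fold change -2.12, SE 0.41, adjusted p = 0.031), the protease inhibitor gene Spint1 (-1.80) and the adhesion molecule gene Epcam (-2.20). The list median was -1.43 (camera adjusted p = 2.64e-08, and adjusted p = 0.152 with an estimated correlation), and Cldn7 was at -2.34 (adjusted p = 0.0561). Of 16 neural genes, 4 were lower (12 adjusted over the list alone, and 11 with that block), with a median of -1.58 (camera adjusted p = 2.98e-10, and adjusted p = 0.123 with an estimated correlation). They were the transcription factor genes Pax6 (-1.86, adjusted p = 0.00396), Sox3 (-2.28, adjusted p = 0.00727), Sox1 (-3.01) and Pax3 (-1.83). Pax6 and Sox3 were called in all 8 fits that leave out 1 library, Cdh1 in 3, and Spint1, Epcam, Sox1 and Pax3 in 2 each. Both lists had their highest level in F among the endothelial libraries and in E among the endocardial libraries. Of 13 endoderm and yolk sac genes, Sox7, which endothelium also expresses, was higher and Epcam, shared with the epithelial list, lower. Adjusted over the list alone 2 were higher and 3 lower, with Trf at 1.35 and Foxa2 at -1.74. The median was -0.08, the mean 0.02 and the camera direction upward (camera adjusted p = 0.881).

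**Figure D4:**
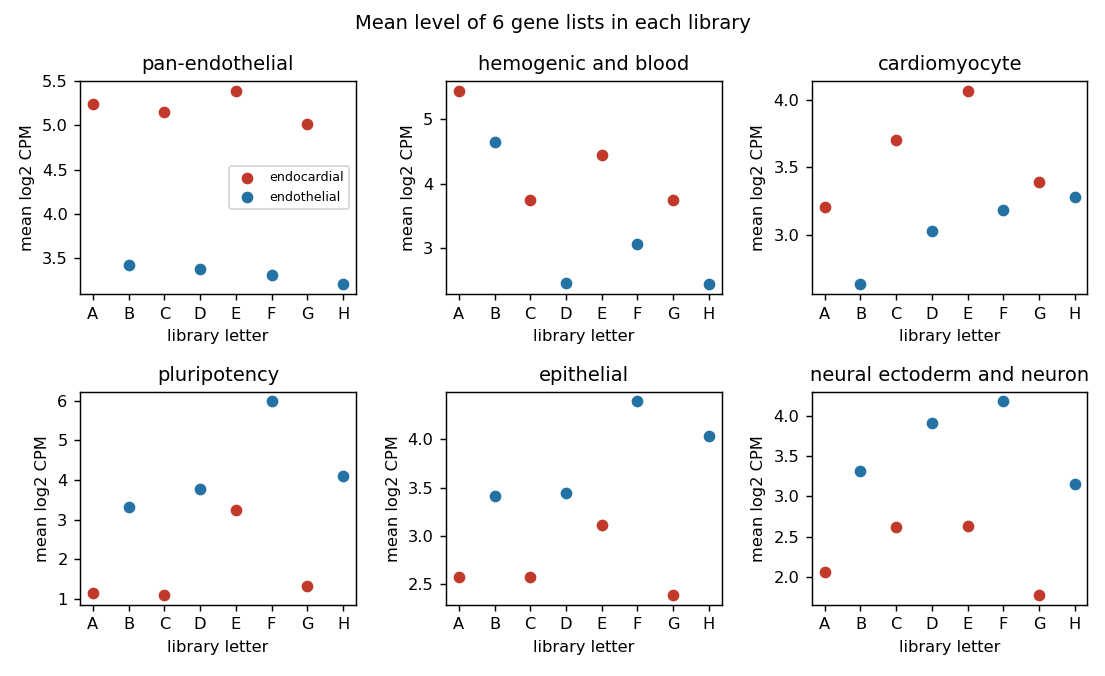
Mean log2 CPM (vertical axes) of the tested members of 6 gene lists in each library (horizontal axes, letters A to H), red for endocardial and blue for endothelial. The pan-endothelial level is above 5.0 in all 4 endocardial libraries and 3.21 to 3.43 in the endothelial ones, and the pluripotency level is highest in F at 5.98.

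Few mesenchymal, smooth muscle and matrix genes were called by edgeR. Of 17 smooth muscle and mural genes, 1 was higher, also when adjusted over the list alone, the smoothelin gene Smtn (log2 fold change 0.63, adjusted p = 0.0412, called in 1 of 8 fits that leave out 1 library). The list's median was 0.29 (camera adjusted p = 0.103), with Cnn1 at 0.88, Myocd at 0.71 and Mylk at -0.83. Camera called the list without a low-count filter (adjusted p = 0.0334) and without A (0.016), D (0.0498), G (0.0465) or H (0.0453). Of 22 genes of the endothelial-to-mesenchymal transition and cushions, edgeR called 0 over all genes and 0 adjusted over the list alone (1 above and 1 below 0 at an unadjusted p under 0.05, and 0 by DESeq2 or limma). Their median was 0.18 (camera adjusted p = 0.199, but 0.0498 without D and 0.0289 without H), with Zeb2 at 0.40, Twist2 at 0.57, Vim at 0.53 and Cdh2 at -0.39. Of 22 mesenchyme and fibroblast genes, edgeR called 0 over all genes and 0 adjusted over the list alone (1 above and 3 below 0 at an unadjusted p under 0.05, 0 by DESeq2 or limma, and 3 lower with neighbouring letters as a block). Ptn was at -1.16, Dlk1 at -0.69, Foxc2 at 0.84 and Dcn, highest in library B, at -1.70 (median -0.17, camera adjusted p = 0.625). Of 10 epicardial genes, edgeR, DESeq2 and limma called 0, and 0 passed adjusted over the list alone (2 below 0 at an unadjusted p under 0.05), with Bnc1 at -1.10, Upk3b at -1.34, Upk1b at -1.53 and Sema3d at -1.16. Their median was -0.48 (camera adjusted p = 0.271, but 0.0254 without F and 0.773 without B). Library B had the highest values of Bnc1 (55.9 CPM), Upk3b (78.9 CPM) and Upk1b (18.2 CPM), and library F that of Sema3d (28.3 CPM). Of 44 matrix genes, 1 was higher, also when adjusted over the list alone, Hapln1 (5 higher and 2 lower with that block). That list's median was 0.05, its mean -0.01 and its camera direction upward (camera adjusted p = 0.552, but 0.0306 without B), with Col13a1 at 0.56, Lama5 at -0.58 and Col4a2 at 0.54. Of 6 skeletal muscle genes, edgeR, DESeq2 and limma called 0, also adjusted over the list alone, with 0 at an unadjusted p under 0.05 (Tnnt3 0.41, Tnnt1 -0.59, Actn3 -0.42, Chrna1 0.36, median 0.20, camera adjusted p = 0.881).

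Among proliferation and metabolic genes, differences were small. Of 30 cell cycle genes, 1 was higher, also when adjusted over the list alone, the mitotic kinase gene Cdk1 at 174 ± 21.4 against 122.7 ± 9.48 CPM (SD, n = 4; adjusted p = 0.049), and it was called in 0 of the 8 fits that leave out 1 library (highest adjusted p = 0.137, without C). Plk1 and Aurka, at 0.41 each, and Ccnb1, at 0.35, were not called. The cell cycle list's median was 0.16 (camera adjusted p = 0.00597, and adjusted p = 0.632 with an estimated correlation, and 0.116 without B). All 22 oxidative phosphorylation genes had a positive log2 fold change, with a median of 0.12 (camera adjusted p = 0.011, and adjusted p = 0.701 with an estimated correlation), and that call ended without B (0.0632) or E (0.375). Of them edgeR, DESeq2 and limma called 0, also adjusted over the list alone, with 0 at an unadjusted p under 0.05 (Ndufv1 0.19, Cox7b 0.43, Cycs 0.34, Atp5o 0.24). Of 19 glycolysis genes, the same 3 tools called 0, also adjusted over the list alone, with 0 at an unadjusted p under 0.05 (Slc2a3 -0.45, Ldha 0.26, Pgk1 0.31, Hk2 -0.13, median 0.04, camera adjusted p = 0.881). Of 18 hypoxia genes they called 0, also adjusted over the list alone, with 1 at an unadjusted p under 0.05 (Egln3 0.51, P4ha2 -0.28, Adm 0.82, Hilpda 0.26, median 0.05, camera adjusted p = 0.613).

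Of 21 sterol synthesis genes, edgeR called 0 over all genes, with Idi1 at 0.27, Pmvk at 0.20 and Cyp51 at -0.14. That list had a median of 0.02, a mean of -0.03 and a downward camera direction (camera adjusted p = 0.972). Of 18 interferon and antigen presentation genes, edgeR, DESeq2 and limma called 0, also adjusted over the list alone, with 2 below 0 at an unadjusted p under 0.05 (Gbp2 -1.08, H2-K1 -0.46, B2m 0.35, Ddx58 -0.70). Their median was -0.22 (camera adjusted p = 0.109, but 0.0457 on ranks and 0.00079 without A). Of 25 immediate early and dissociation genes, the same 3 tools called 0, also adjusted over the list alone, with 0 at an unadjusted p under 0.05 and 3 called higher with neighbouring letters as a block (Myc 0.66, Hspb1 -0.44, Zfp36 0.55, Egr3 0.75). Their median was 0.13 (camera adjusted p = 0.625, but 0.00209 without H), and their mean level was 6.80 log2 CPM in G and 6.69 in H against 4.40 to 5.22 in the other 6 libraries.

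Shares of counts from whole gene classes did not differ beyond the spread between libraries, in 7 two-sided exact permutation tests whose smallest possible p is 0.0286. Mitochondrial genes took 4.42% ± 1.41 of counts in the endocardial and 4.89% ± 1.23 in the endothelial libraries (SD, n = 4). Ribosomal protein genes took 4.78% ± 1.47 and 4.21% ± 0.66, histone genes 0.201% ± 0.0326 and 0.175% ± 0.00812, and the 10 most abundant genes 6.71% ± 0.795 and 7.05% ± 0.986. Cardiomyocyte genes took 0.0468% ± 0.0121 and 0.0325% ± 0.0104 (exact p = 0.114, adjusted p = 0.8) and endoderm and yolk sac genes 0.201% ± 0.0203 and 0.225% ± 0.0657 (exact p = 0.543, adjusted p = 0.8).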

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

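The tests of the pan-endothelial, pluripotency and neighbouring-letter patterns were chosen after those patterns were seen, as was the restriction to splits that part neighbouring letters, and the counts over all other splits of the libraries were planned.

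Other splits of the 8 libraries into 4 and 4 bear on whether the groups could have been drawn by chance. In 1 of the 35 splits, the real one, as many as 356 genes were called, and the highest of the others called 1. The same held for the 284 genes that differed at least 2-fold, with 1 of 35 splits and a highest other of 1. If the libraries can be exchanged freely, chance was thus unlikely for the gene counts, though 1 of 35 is the smallest share possible and cannot exclude it. The joint deviation of neighbouring letters, given below, speaks against free exchange. For the lists chance stayed open. In 5 of the 35 splits camera called 14 or more lists, and the highest other split called 18. If neighbouring letters are pairs, only the 8 splits that part every pair count, which are too few for a share under 0.125. Among these 8 the highest other split called 0 genes and 15 lists. The exact p-values of 0.0286 below rest on free exchange as well.

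In the libraries labelled endothelial, pan-endothelial transcripts were lower than in those labelled endocardial. Dilution of a single endothelial profile by cells lacking these transcripts would lower all 30 genes by a common factor. To test this, each gene's difference from the list mean was divided by a standard error. That error was recomputed in each split from log2 CPM and is not edgeR's. The spread was larger than in any other split (339 against 192 at most, and 66.7 over the splits that part neighbouring letters, exact permutation p = 0.0286, the smallest these groups can give). This was the last of 3 tests, each chosen after the one before was seen, since Cochran's Q (387 at 29 degrees of freedom) treats genes as independent and the unweighted spread, which lets imprecise genes such as Tek count as much as precise ones, did not exclude it (13.8 against 14.9 at most, and 6.83 over the splits that part neighbouring letters, exact permutation p = 0.0571). A lower endothelial share that raises all other cell types alike would keep the pluripotency and cardiomyocyte levels in step. Their difference instead differed between the groups (two-sided exact permutation p = 0.0286). Both levels had been seen before this test was chosen, so it cannot exclude such a share. Library F alone does not carry the pattern, since the median was 1.88 without it, while mixing with cells that hold some of these transcripts, and a difference between the labelled cell types, stay open as untested.

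Pluripotency transcripts were higher in the libraries labelled endothelial, most of all in F. Library F was not the only source, because without it the list's median moved from -2.99 to -1.86 (camera adjusted p = 1.89e-11, but 0.253 with an estimated correlation). That median remained below -1, a limit set after the values were seen. The list level, endocardial minus endothelial log2 CPM, was -2.17 for A and B, -2.67 for C and D, -2.73 for E and F and -2.78 for G and H. Different shares of undifferentiated cells in the sorted samples are a candidate explanation, since members of the list moved together within groups, with a mean correlation of 0.725 where 95% of random lists of matched expression lay below 0.13. That test is not specific to cell shares, because immediate early genes, which do not mark a cell type, reached 0.815 and hemogenic genes 0.614. Pluripotency genes kept on in the sorted cells themselves remain open as well, and the sort markers that would bear on this are not given in the sources used here.

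Libraries with neighbouring letters deviated from their group means together. Of the 24 ways to pair the libraries across groups, the neighbouring letters ranked 1, with a mean correlation of 0.457 across genes against 0.287 for the next. Within their own groups, E and F had the highest pluripotency, epithelial and neural levels, A and B the highest hemogenic level, and G and H the highest immediate early level. Shared preparation of neighbouring letters, such as a culture or sort in common, may account for this, but no label says so and none of these was told apart from the others. No biological explanation was tested, and the lists here were picked from 30 after their levels were seen. Not all lists paired in this way. Within the groups, the pan-endothelial level was highest in E and B, and the cardiomyocyte level in E and H.

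Single libraries that stood far from the other 3 of their group were found for 15 of 370 groups of 4 values, where chance, marking about 1 in 20, gives 18.5 (Dixon's test at 5%, and each last value in brackets below is the gap to the nearest library as a part of the group's range). Library F stood apart among the endothelial libraries for Pou5f1 (6.58 log2 CPM against 4.63 to 4.79, 0.919 of the range) and Fut9 (3.73, others up to 1.98, 0.872). It was low for Hapln1 (4.95, others from 5.51, 0.885), Zeb2 (5.58, others from 6.13, 0.841) and the level of the endocardial list (4.62, others from 5.01, 0.842). Library E stood apart among the endocardial libraries for Pou5f1 (3.55 against 0.76 to 1.02, 0.905), the pluripotency level (3.25 against 1.09 to 1.32, 0.895), Pdgfb (5.14, others up to 4.68, 0.847), Cox7b (7.15, others up to 6.31, 0.954) and Cycs (5.98, others up to 5.26, 0.919). Library A was low among the endocardial libraries for Dll1 (1.73, others from 2.11, 0.91) and Aurka (6.01, others from 6.37, 0.879). Library B was high among the endothelial libraries for Dcn (6.36, others up to 3.86, 0.926) and the hemoglobin share (0.254%, others up to 0.0367%, 0.948). Library D was low for Adgrl4 (0.32, others from 1.18, 0.877).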

How the results depend on the processing

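The block of neighbouring letters was chosen after the data were seen, and all other settings were planned. The labels give each library a letter of its own and state no pairing, so the block rests on the data alone.

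Counts of called genes moved with the tool, the block, the threshold and single libraries. DESeq2 called 860 genes (330 higher and 530 lower, with 46 adjusted p-values not given), of which 354 were among the 356, and at least 2-fold 597 (397 lower). Limma with voom weights called 975 (410 higher, 565 lower), sharing 355, and at least 2-fold 570 (359 lower). With the added block of neighbouring letters 1204 genes were called (505 higher, 699 lower), sharing all 356, and at least 2-fold 739 (256 higher, 483 lower). With the block, the largest moves among lists were in hemogenic genes (18 higher), pluripotency (15 lower), epithelial (11 lower) and neural genes (11 lower). Of 83 genes selected for naming and not called, the block gained 33, among them, of those fixed in advance, Bmp2, Edn1 (adjusted p = 0.0412), Runx1 (0.00484), Etv2 (0.0247) and Hey2 (0.02), and it lost 0 of those called. At an adjusted p below 0.01 there were 104 (83 higher, 21 lower), and at least 2-fold 96 (78 and 18), as a stricter threshold must give. Leaving out 1 library gave 135 to 457 genes (99 to 230 higher, 35 to 227 lower) and at least 2-fold 120 to 380 (91 to 183 higher, 29 to 197 lower). The cause of these shifts was not tested. Scaling, filters, abundant genes and estimation without robustness gave 337 to 365 genes, and 1 surrogate variable 463. The 356 genes kept their sign in every setting where they were tested, and the median log2 fold change of all genes stayed within 0.0276 of 0.

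Camera called 14 lists, but 1 with an estimated correlation, and fry called 9. With the added block and an estimated correlation the pan-endothelial list had an adjusted p of 0.0663. The first principal component held 41.3% of the variance with all tested genes.

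Lists not called in the comparison turned their direction without passing the threshold. On ranks this held for BMP, endoderm and sterol genes (adjusted p = 0.981 each), without a low-count filter for BMP (0.838), mesenchyme (0.931) and sterol genes (0.76), with 1 surrogate variable for immediate early genes (0.994) and with the block for BMP (0.989), endoderm (0.985) and sterol genes (0.957). Leaving out 1 library turned BMP (adjusted p over these fits 0.417 to 0.84), Wnt (0.426 to 0.938), endoderm (0.65 to 0.926), sterol (0.675 to 0.936), mesenchyme (0.183 to 0.974), skeletal muscle (0.389 to 0.908), immediate early (0.00209 to 0.939), glycolysis (0.213 to 0.938) and matrix genes (0.0306 to 0.723) in some fits. The immediate early value of 0.00209 (without H) and the matrix value of 0.0306 (without B) came from fits that kept the direction. Log2 fold changes that changed sign were not called. They were those of Tek (-0.20 to 0.47 over these fits), Hand2 (-0.27 to 0.15, and 0.0592 with the block) and Egr3 (-0.33 to 1.95). The same held for differences in share, in percentage points, of hemoglobin (-0.0295 to 0.05), endoderm (-0.0483 to 0.00162), the 10 most abundant (-0.679 to 0.107), mitochondrial (-1.08 to 0.0582) and ribosomal protein genes (-0.125 to 1.02). The cause was not tested. Of 62 named genes that were called, 32 were called in all 8 fits that leave out 1 library and 30 were not. Depth limits genes below the 0.264 to 0.449 CPM that a count of 0 allows.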

Other observations

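The genes in this part were named after their values were seen, and so was the test over gene families.

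The transcription factor genes Six3, Lhx2, Lhx5 and Otx1, which are in no list, were lower in the endocardial libraries by edgeR. Six3 had a log2 fold change of -2.60, Lhx2 of -2.48, Lhx5 of -2.78 and Otx1 of -2.46 (adjusted p = 0.0276, 0.00629, 0.0118 and 0.033). Of 5 tested genes of the Pax family of transcription factors, 4 were lower, namely Pax2, Pax3, Pax5 and Pax6. That share was larger than among all tested genes (Fisher's exact test, one-sided, adjusted p = 7.6e-05 over 886 families and directions of gene symbols). Fisher's test treats genes as independent, although all were measured in the same libraries, so its p-value does not measure the spread between samples. No other family passed that test, and the next, cadherin genes lower in the endocardial libraries, had an adjusted p of 0.138. Pax3 and Pax6 are also in the neural list, so the Pax result is not independent of it. Pax6 was called in all 8 fits that leave out a single library, but Pax3 in only 2 of the 8.

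Higher in the endocardial libraries, and also in no list, was the sphingosine-1-phosphate receptor gene S1pr1, with a log2 fold change of 1.74 and, for the transporter gene Spns2, which exports that lipid, of 1.78 (adjusted p = 0.00154 and 0.0402). Calcrl, the receptor subunit for adrenomedullin, had 1.66 and the adenosine receptor gene Adora2a 2.35 (adjusted p = 0.000143 and 0.00726). The called genes were not unevenly spread over the chromosomes, with an adjusted p of 1 for each of 20 tested by Fisher's exact test.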
